A study of Mus musculus with 35 samples.

How the data were processed

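Gene expression was measured by RNA sequencing in regulatory T cells (Tregs), the CD4+ T cells that restrain immune responses. Tregs were sorted in 2 rounds of flow cytometry as CD4+ CD25+ cells, 1000 cells per library, from visceral adipose tissue (VAT) and spleen. The mice were male wild-type C57BL/6 retired breeders, over 35 weeks old and kept in 12 h of light and 12 h of dark. Tissue was taken at Zeitgeber times (ZT, hours after lights on) 0, 4, 8, 12, 16 and 20. Each of the 12 groups of tissue and time had 3 libraries, except VAT at ZT20, which had 2, for 35 libraries in all (17 VAT, 18 spleen). Libraries are named by tissue, time and the replicate letter of the labels. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be technical.

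Per the labels' protocols, RNA was primed with oligo-dT, amplified in a limited number of PCR cycles, made into libraries with Nextera XT and sequenced on a NextSeq500 as paired reads of 25 nt. The deposited values were raw counts of reads per gene symbol for 55011 symbols, made by the authors with STAR 2.7.3a and featureCounts on mm10, per the submitters' processing notes. The featureCounts version, the annotation, the strand setting and the handling of reads that match several places are not given in the sources used here. Without strand, reads of overlapping or antisense genes cannot be told apart, and near-identical copies such as Hspa1a and Hspa1b, or members of the Gbp, Ifit and Slc28a2 families, are uncertain. No molecular identifiers were used, so amplified copies are not independent molecules. Oligo-dT priming followed by amplification can favour short or long transcripts to an extent that varies between libraries, which was measured as described further on.

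The libraries held 2069319 to 6260185 counts, with medians of 4104617 in VAT and 3181086.5 in spleen. Of the 34 pairs of libraries within a group, none agreed within sampling noise: the chi-square statistic per gene ran from 4.1 to 20. Positions are whole genes in the GENCODE M21 annotation of GRCm38 (mm10), counted from 1. 52936 of the symbols matched it by name.

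Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 12 groups, which left 15910 genes, and libraries were scaled with trimmed mean of M values (TMM) factors. Dispersions and quasi-likelihood fits were robust. The contrast of VAT with spleen was the mean of the 6 VAT groups minus that of the 6 spleen groups. Rhythm was tested with a cosine and a sine of a 24 h period in each tissue (2 degrees of freedom), in 1 model over both tissues, and the difference in rhythm as the difference of those terms. Amplitudes are peak to trough on the log2 scale. All of these are edgeR quasi-likelihood tests with Benjamini-Hochberg adjustment over the 15910 genes and a threshold of 0.05, and adjusted p values below come from them unless another test is named. Levels are CPM (counts scaled to the library's total after TMM), given as mean ± SD over libraries, and log2 fold changes and amplitudes as estimate ± SE. Fold changes of genes near 0 in a tissue depend on the prior count of the fit. Log2 CPM for scores used a prior count of 2.

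The tests of genes, of gene lists between tissues and of list scores over time, most alternatives, 17 gene lists, 12 lists of markers of other cell types and the rule for naming genes were fixed before the data were examined. The test of a list's difference in rhythm between tissues was added after seeing the data. The gene lists were core clock, glucocorticoid-responsive, heat shock, cold-inducible, immediate early, Treg core, VAT Treg signature, lymphoid or resting Treg, activation and effector, trafficking receptors, sterol and fatty acid synthesis, lipid uptake and storage, fatty acid oxidation, oxidative phosphorylation, glycolysis, proliferation and interferon response. They were written from general knowledge, and some genes are in 2 of them, such as Nfil3 and Bhlhe40 in core clock and VAT Treg signature and Per1 in core clock and glucocorticoid-responsive. Between tissues the lists were tested with camera (limma 3.58.1), at a preset correlation of 0.01 and again with an estimated correlation. Over time each list was given a score per library, the mean over members of log2 CPM minus the gene's mean in the tissue. The score's fit to the 24 h cosine and sine was tested with 100000 permutations of the times within the tissue. The difference between tissues was tested with 20000 permutations of the tissue labels within each time. Both were adjusted by Benjamini-Hochberg over the 17 lists. Marker lists for B cells, CD8 T cells, conventional CD4 T cells, macrophages or monocytes, dendritic cells, neutrophils, NK cells or ILCs, adipocytes, stromal or mesothelial cells, endothelial cells, erythroid cells and plasma cells were summed as CPM and compared by two-sided permutation tests.

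Named genes were, between tissues, the 12 with the largest rise and the 12 with the largest fall among those past the threshold, with an average log2 CPM of at least 5 and the same direction at all 6 times. For rhythm they were the 15 with the largest amplitude past the threshold and an average log2 CPM in the tissue of at least 5, and for the difference in rhythm the 10 with the lowest p at that level. All core clock genes, Foxp3, and 2 to 4 members with the lowest p of each other list were named as well. Predicted gene models, immunoglobulin and T cell receptor segments, ribosomal protein, mitochondrial and Y-linked genes and Xist were not named. Any other gene named was chosen after its values were seen, and the text says so. Some genes that these rules select are not reported here.

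After a first run on the real counts, the steps were tested on simulated counts with the means, dispersions and library sizes of the 15910 genes. The 200 changed genes were drawn from those with an average log2 CPM of at least 5. Recovery at lower levels was not simulated. For VAT against spleen the test found 94% of genes changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, with 7 false calls. For rhythm in VAT it found 13.4%, 85.1% and 98.5% of genes with amplitudes of 0.5, 1 and 2, with 2 false calls, and the median error of the peak was 0.9, 0.5 and 0.3 h. For the difference in rhythm it found 3%, 49.3% and 93.9% at those amplitudes, with 2 false calls. In the spleen, where no gene was changed, there were 0 false calls by the same edgeR test. Camera and the list score test each called the changed list and 0 of 16 unchanged lists. Simulated genes varied independently, without trends between libraries. Members of the real lists were correlated, with estimates up to 0.41 for oxidative phosphorylation. The false calls counted here therefore do not cover such correlation or trends. Amplitudes near 0.5 were therefore mostly below what these libraries could detect gene by gene.

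The alternatives were relative log expression factors, no filter, an average log2 CPM of at least 5, a 2-fold minimum, detected genes as a covariate, limma voom with sample quality weights, DESeq2 1.42.0, a test of any difference between the 6 times (5 degrees of freedom), each tissue fitted alone, the replicate letter as a block, and leaving out each library in turn. After seeing the data, 4 were added: the transcript-length slope of each library as a covariate, that slope with the GC slope, leaving out the ZT20 libraries, and library totals without TMM factors. The length slope of a library is the slope of its log2 CPM deviation from the tissue mean on log2 transcript length, fitted with GC content over 5528 of the 5565 genes with an average log2 CPM of at least 5. For rhythm in a tissue, the replicate block gave each letter of that tissue its own level over all times. Letter D occurred only at ZT4, ZT8 and ZT12 and letter A never at ZT4 or ZT8. That block is therefore partly confounded with time and can remove rhythm. For the tissue contrast and the difference in rhythm, the block instead paired VAT and spleen libraries of the same time and letter. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.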

Results

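Transcripts were counted in Tregs sorted from VAT and spleen at 6 times of the light and dark cycle. The series set the daily course of gene expression in Tregs of adipose tissue, a population that lives in fat and carries its own receptor and transcription factor profile, beside that of Tregs from a lymphoid organ. The design gave 3 comparisons: VAT against spleen, the course over time within each tissue, and the difference between those courses. Depth ranged from 2069319 to 6260185 counts per library over 17 VAT and 18 spleen libraries.

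To compare the tissues, levels were averaged over the 6 times. The labels do not vary handling before the sort within a tissue, so handling and tissue cannot be separated for any gene. Foxp3 (chromosome X, 7573644 to 7595245), the lineage-defining transcription factor of Tregs, was measured at 711 ± 67.2 CPM in VAT (SD, n = 17) and 521 ± 56 CPM in spleen (SD, n = 18), and was higher in VAT at 6 of 6 times. Its log2 fold change was 0.45 ± 0.05, with an adjusted p of 2.4e-10 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. VAT Tregs had high levels of Cxcl2, a neutrophil-attracting chemokine (chromosome 5, 90903871 to 90905938; 943 ± 202 against 0.558 ± 0.706 CPM, log2 fold change 11.35 ± 0.18). Areg, which encodes the growth factor amphiregulin (chromosome 5, 91139599 to 91148432), was at 2490 ± 610 against 4.79 ± 6.85 CPM (9.50 ± 0.27). Il1rl1, the gene of the alarmin receptor ST2 (chromosome 1, 40429570 to 40465415), averaged 1470 ± 189 against 12 ± 5.87 CPM. Gata3, a transcription factor of type 2 responses (chromosome 2, 9857078 to 9890034), averaged 1870 ± 273 against 175 ± 29.4 CPM (3.44 ± 0.07). Dtx1, a ubiquitin ligase of the Notch pathway (chromosome 5, 120680202 to 120711927), was lower in VAT, at 0.328 ± 0.488 against 63.1 ± 22 CPM (-8.18 ± 0.24).

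Of the 15910 genes tested, 9896 differed between the tissues, 4520 higher and 5376 lower in VAT, and 2126 and 2614 of these did so by at least 2-fold. Among the genes that differed, 77.7% had the same direction at all 6 times. The other genes with the largest rises in VAT were AA467197 (10.98), the stress-induced transcription factor gene Atf3 (10.89 ± 0.30), the chemokine receptor gene Ccr1 (9.36) and the potassium channel gene Kcna4 (9.01). They were followed by Fos (8.97 ± 0.25), Fosb (8.89), Anxa1 (8.95), the proprotein convertase gene Pcsk1 (8.92), the leukotriene B4 receptor gene Ltb4r1 (8.34) and the cell cycle inhibitor gene Cdkn1a (8.18). The other largest falls were Treml2 (-6.87), Slc28a2b (-6.56), Nsg2 (-6.23), and Cxcr5, the receptor for homing to B cell follicles (-6.21 ± 0.29). They were followed by the interferon-induced GTPase genes Gbp2b (-5.82) and Iigp1 (-5.82), Igfbp4 (-5.70), Ifit1bl1 (-5.48), Dpp4 (-5.25) and Nod1 (-5.21). Slc28a2b, Gbp2b, Iigp1 and Ifit1bl1 belong to families with close copies, between which reads can be split. With library totals in place of TMM factors, 2856 genes were higher and 8514 lower, and 660 of the 4520 genes turned negative, 134 of them past the threshold. That scaling moved the median log2 fold change of all genes from -0.105 to -0.45, a shift of -0.345, so the direction of small changes is relative to the scaling.

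The VAT Treg signature list rose in VAT (camera adjusted p = 1.2e-32; 3.93e-08 with an estimated correlation): 21 of 24 members were higher and 0 lower, by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, against 9896 of 15910 genes that differed at all. Among them were Pparg, the nuclear receptor of adipocyte and fat-resident Treg programs (107 against 1.25 CPM, 6.33 ± 0.25), Il9r (5.05 ± 0.16) and the chemokine receptor gene Ccr2 (2220 against 21.4 CPM, 6.69 ± 0.24). Tnfrsf9 (0.24 ± 0.13), Gpr55 (-0.06 ± 0.24) and Lpl (-0.50 ± 0.73) did not pass. The lymphoid or resting Treg list fell (camera adjusted p = 6.22e-20; 1.22e-05 with an estimated correlation), with 12 of 14 members lower and 1, Ly6c1, higher. Bach2, a repressor that keeps T cells quiescent, fell by 5.02 ± 0.15 on the log2 scale, Lef1 by 2.33 ± 0.08 and Foxp1 by 1.54 ± 0.06. The activation and effector list rose (camera adjusted p = 3.16e-09; 0.00829 with an estimated correlation), with 11 of 16 members higher, such as the early activation antigen gene Cd69 (4090 against 319 CPM, 3.72 ± 0.07), the adhesion receptor gene Cd44 (2.99 ± 0.07), Maf (2.39 ± 0.07) and the cytokine gene Tnf (2.33 ± 0.07), and 3 lower. The Treg core list split into 7 members higher and 5 lower. Ctla4 (2.49 ± 0.06), Capg (1.78 ± 0.06) and Tnfrsf18 (1.55 ± 0.06) were higher, Izumo1r (-3.25 ± 0.10) was lower. Its median log2 fold change was 0.55 and its mean -0.36, and its camera adjusted p of 0.0234 became an adjusted p = 0.214 with an estimated correlation.

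Of the trafficking receptors, 10 of 20 were higher in VAT and 10 lower (camera adjusted p = 0.88). Higher were Ccr2 and Cxcr4 (2.22 ± 0.12), lower was S1pr1, the receptor for exit from lymphoid organs (-1.92 ± 0.08). The interferon response list fell in VAT (camera adjusted p = 9.13e-10; 0.00911 with an estimated correlation), with 14 of 18 members lower and 2 higher. Among the lower ones were Ifi47 (-2.12 ± 0.06), Gbp2 (-2.28 ± 0.07) and Rtp4 (-5.18 ± 0.19).

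Immediate early genes, which answer stimulation within minutes and are also induced when tissue is dissociated, were higher in VAT in 19 of 20 cases (camera adjusted p = 8.63e-68; 2.3e-09 with an estimated correlation), and Egr2 was lower (-1.11 ± 0.16). Junb averaged 19200 against 371 CPM (5.73 ± 0.07), Fos 6000 ± 1180 against 12.6 ± 8.77 CPM, Zfp36 598 against 36 CPM (4.08 ± 0.07), Klf6 2060 against 267 CPM (2.95 ± 0.05) and Btg2 2670 against 303 CPM (3.14 ± 0.05). The lowest VAT library for Fos held 4560 CPM and the highest spleen library 33.1 CPM. The glucocorticoid-responsive list rose (camera adjusted p = 2.78e-08; 0.000225 with an estimated correlation), with 8 of 13 members higher and 3 lower. Dusp1, a phosphatase that is also an immediate early gene, averaged 6970 against 89.8 CPM (6.36 ± 0.08), Per1 182 ± 36.8 against 27.4 ± 6.91 CPM, and Il7r 879 against 378 CPM (1.22 ± 0.06). Pik3ip1 was lower (-1.65 ± 0.08). Of the heat shock list 10 of 15 members were higher and 2 lower (camera adjusted p = 0.0313), a call lost at an adjusted p = 0.387 with an estimated correlation. Dnaja1 (1.47 ± 0.07), Bag3 (1.92 ± 0.14), Dnajb1 (1.00 ± 0.09) and Hspa8 (0.80 ± 0.06) were higher. Of the cold-inducible list Rbm3 (0.31 ± 0.05), Cirbp (0.40 ± 0.09) and Srsf5 (0.16 ± 0.06) were all called higher (camera adjusted p = 0.428), but with library totals the values of Rbm3 and Srsf5 were -0.04 and -0.19.

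The lipid uptake and storage list rose in VAT (camera adjusted p = 5.08e-05; 0.000445 with an estimated correlation), with 10 of 15 measured members higher and 1 lower. Plin2, which coats lipid droplets, averaged 609 against 19.1 CPM (5.03 ± 0.13), Hilpda, an inhibitor of lipolysis, 534 against 17.9 CPM (4.90 ± 0.11), and Dgat1, an enzyme of triglyceride synthesis, 655 against 39.2 CPM (4.01 ± 0.11). Lipa, the lysosomal acid lipase gene, was lower (-1.16 ± 0.06). Fatty acid oxidation had 12 of 15 members higher and 0 lower, among them Acadl (1.11 ± 0.07), Etfb (1.59 ± 0.12), Acadvl (0.96 ± 0.07) and Ucp2 (0.72 ± 0.06). Its camera adjusted p of 0.000386 became an adjusted p = 0.0589 with an estimated correlation. Sterol and fatty acid synthesis had 16 of 22 members higher and 1 lower, the higher ones including Insig1 (1.54 ± 0.09), Sc5d (0.91 ± 0.06) and Elovl6 (1.32 ± 0.11). Its camera adjusted p of 0.00966 became an adjusted p = 0.343 with an estimated correlation. Glycolysis had 11 of 15 members higher and 1 lower, with Pkm (0.83 ± 0.04), Aldoa (1.06 ± 0.06), Tpi1 (0.96 ± 0.08) and Gapdh (0.76 ± 0.06). Its camera adjusted p of 0.00969 became an adjusted p = 0.164 with an estimated correlation. Oxidative phosphorylation was not called (8 of 23 members higher, 1 lower, camera adjusted p = 0.701), with Ndufa4 lower (-1.56 ± 0.12) and Sdhb (0.37 ± 0.06), Cox6a1 (0.58 ± 0.09) and Cox5a (0.41 ± 0.08) higher. Proliferation was not called either (8 of 20 higher, 4 lower, camera adjusted p = 0.559), with Mki67 (2.20 ± 0.15) and Pcna (0.68 ± 0.07) higher, Mcm7 (-0.72 ± 0.09) and Mcm4 (-0.40 ± 0.08) lower. In each of the 17 lists the number of members called was the same when adjusted over the list alone.

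**Figure D1:**
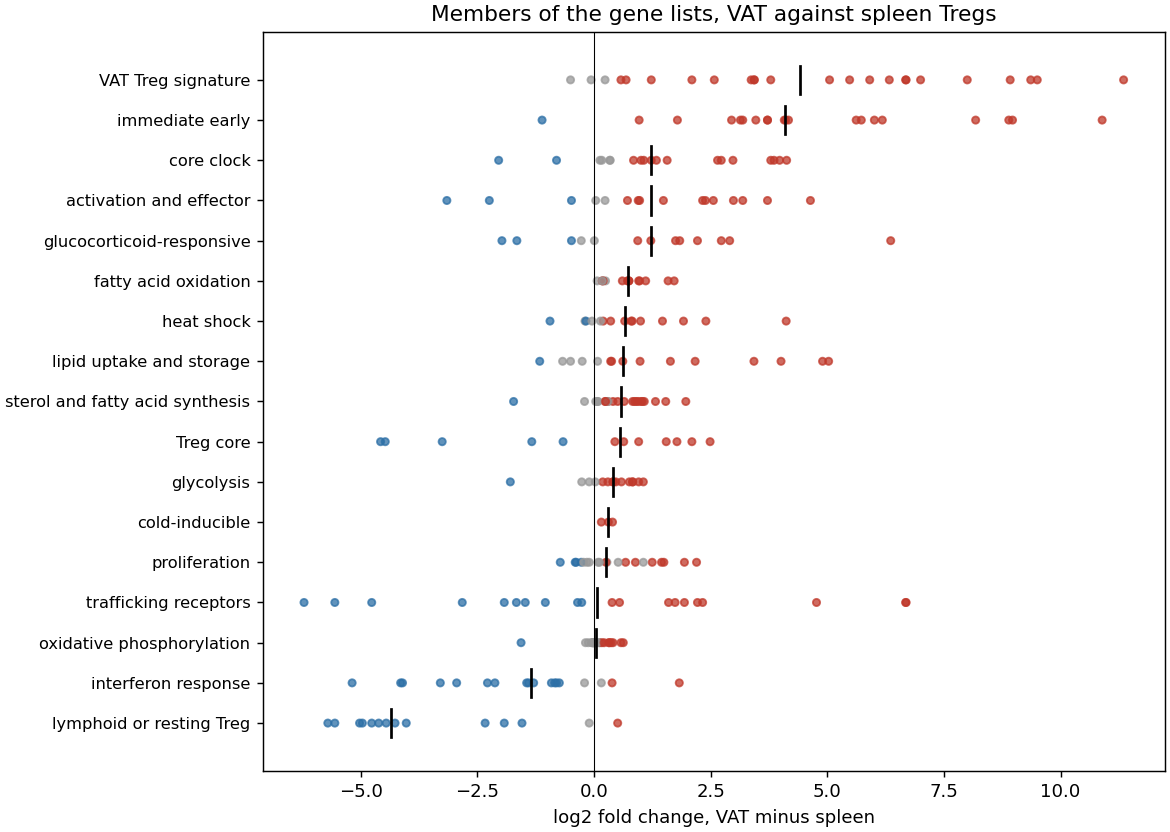
Log2 fold change of VAT against spleen (x axis) for each measured member of the 17 gene lists (y axis), with 1 point per gene: red for genes called higher in VAT, blue for lower, grey for not called, and a black bar at the list's median. The medians ran from -4.35 for lymphoid or resting Treg to 4.42 for VAT Treg signature genes; with library totals values moved by about -0.345, which turned 15 of the 163 members called higher negative, 4 of 8 in oxidative phosphorylation, 3 of 16 in sterol and fatty acid synthesis, 2 of 3 in cold-inducible, 2 of 12 in fatty acid oxidation, 2 of 11 in glycolysis, 1 of 10 in heat shock and 1 of 8 in proliferation.

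Markers of other cells were measured in the same libraries as summed CPM and compared by permutation. B cell markers were at 229 ± 68.3 CPM in VAT and 1950 ± 491 CPM in spleen, of which Ighm made up 159 and 1800 CPM. Neutrophil markers were at 450 ± 167 against 11 ± 4.49 CPM, nearly all of it the matrix protease gene Mmp9, while the neutrophil gene S100a8 was at 0.0326 against 0.0133 CPM. Stromal or mesothelial markers were at 200 ± 20.5 against 36.8 ± 9.66 CPM, with Gsn at 102 against 28.1 CPM and Lrrn4 at 91.8 against 3.67 CPM. Macrophage or monocyte markers (15.5 ± 4.97 against 77.9 ± 25 CPM), endothelial markers (35.8 ± 8.38 against 259 ± 45.6 CPM, mostly Pecam1), adipocyte markers (16.5 ± 6.13 against 25.9 ± 4.81 CPM) and erythroid markers (3.87 ± 1.97 against 14.8 ± 23.9 CPM) were lower in VAT. Plasma cell markers (270 ± 34.7 against 169 ± 60.3 CPM, mostly Xbp1), conventional CD4 T cell markers (56.5 ± 23.6 against 25.5 ± 5.34 CPM), NK cell or ILC markers (24.6 ± 10.9 against 3.14 ± 1.23 CPM, mostly Il5) and dendritic cell markers (27.8 ± 10.5 against 17.8 ± 6.02 CPM) were higher. Most of the adipocyte sum was Lipe (13.9 against 24.3 CPM), and most of the conventional CD4 T cell sum was Cd40lg (52.4 against 22.3 CPM). Of the dendritic cell markers, Xcr1 was higher in VAT (20.1 against 0.477 CPM) and Zbtb46 lower (5.9 against 15.4 CPM). CD8 T cell markers, at 15 ± 9.56 against 12.6 ± 4.28 CPM, did not differ by the test (permutation adjusted p = 0.952). The adjusted permutation p was 0.000862 for dendritic cells and 1.2e-05, the smallest these permutations can give after adjustment, for the other 10 lists. Over time, B cell markers in spleen (adjusted permutation p = 0.0288) and plasma cell markers in VAT (0.0144) changed, and the other marker lists were not called in either tissue.

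The core clock was the group the sampling over the day addressed. Between tissues, 15 of its 19 genes differed by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, both over all genes and adjusted over the list alone, 13 of them higher in VAT (camera adjusted p = 1.44e-06; 0.000206 with an estimated correlation). Rora, a nuclear receptor that activates Arntl (chromosome 9, 68653786 to 69388246), was at 1300 ± 131 CPM in VAT and 74.9 ± 16 CPM in spleen (4.13 ± 0.07). Arntl itself, which encodes the activator BMAL1 (chromosome 7, 113207465 to 113314126), was at 110 ± 30.1 against 51 ± 8.91 CPM (1.07 ± 0.08). The repressor gene Per1 (chromosome 11, 69095217 to 69109960) was higher in VAT (2.73 ± 0.07) and Per2 (chromosome 1, 91415982 to 91459324) lower, at 2.72 ± 2.07 against 8.69 ± 3.6 CPM (-2.04 ± 0.24). Also higher were Npas2 (3.98 ± 0.54), Hlf (3.86 ± 0.26), Nfil3 (3.79 ± 0.22), Bhlhe41 (2.98 ± 0.69), Nr1d1 (2.65 ± 0.18), Per3 (1.57 ± 0.16), Ciart (1.34 ± 0.28), Bhlhe40 (1.23 ± 0.17), Nr1d2 (1.01 ± 0.21) and Cry1 (0.85 ± 0.11), and Cry2 was lower (-0.80 ± 0.14). Among those that did not pass were Clock (0.17 ± 0.09), Dbp (0.34 ± 0.16) and Tef (0.13 ± 0.10).

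The course over 24 h in VAT Tregs was then examined. Tef, a PAR bZIP output gene of the clock (chromosome 15, 81802421 to 81826863), rose from 18.2 CPM at ZT20 to 57.7 CPM at ZT12, with an amplitude of 1.56 ± 0.21 and a peak at ZT10.28 (adjusted p = 0.000613, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Per2 peaked at ZT13.21 with an amplitude of 3.04 ± 0.53, from a mean of 0.533 CPM at ZT0 to 5.44 CPM at ZT12. This rested on only 169 counts over all VAT libraries. Nr1d2, the gene of the repressor REV-ERB beta (chromosome 14, 18204054 to 18239127), peaked at ZT9.43 (1.85 ± 0.44), and Arntl at ZT0.24 (0.76 ± 0.17). These 4 core clock genes passed over all genes. With the replicate block Arntl (0.0879) and Nr1d2 (0.123) did not pass over all genes by edgeR, nor did Arntl without the ZT20 libraries (0.0666). The letters were unevenly spread over the times, so the block can also remove rhythm. Adjusted over the list alone 7 of 19 passed, with Per1 (0.61 ± 0.16, peak ZT13.04), Per3 (1.27 ± 0.34, ZT11.64) and Bhlhe41 (3.14 ± 1.15, ZT8.68, at 3.3 CPM). Among those that did not pass in VAT were Clock, Npas2, Cry1, Cry2, Nr1d1, Rora, Dbp, Hlf, Nfil3, Bhlhe40 and Ciart. With the length slope as a covariate, chosen after seeing the data, the amplitude of Nr1d2 fell to 0.78 (adjusted p = 0.329 over all genes, 0.0237 over the list, by edgeR). Over the list Nr1d1 (0.99 to 1.59, 0.00566) and Dbp (0.56 to 1.15, 0.0454) were then called and Bhlhe41 was lost (0.214), as it was with the replicate block (0.192).

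In VAT 299 of 15910 genes were rhythmic (2789 at an unadjusted p under 0.05), by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Their median amplitude was 0.74, and 197 peaked between ZT18 and ZT2. Beside Nr1d2 and Tef, the largest amplitudes were those of Camk2b (1.77 ± 0.41, peak ZT9.24), the acetate-activating enzyme gene Acss1 (1.42 ± 0.26, ZT8.61), Klf11 (1.35 ± 0.29, ZT7.92), Tollip (1.31 ± 0.29, ZT8.84), and Olfr1258 (1.29 ± 0.29, ZT8.32). They were followed by the cholesterol synthesis genes Fdft1 (1.25 ± 0.24, ZT18.93) and Hsd17b7 (1.19 ± 0.28, ZT19.74), the histone demethylase gene Kdm3a (1.24 ± 0.25, ZT8.17), Herc3 (1.13 ± 0.23, ZT9.36), Lpar6 (1.13 ± 0.20, ZT22.74), Galm (1.11 ± 0.19, ZT22.98), Slc14a1 (1.08 ± 0.23, ZT6.9) and Fkbp4, a cochaperone of steroid receptors (1.05 ± 0.16, ZT20.13). The count fell to 28, of which 21 were among the 299, with the transcript-length slope of each library in the model, and to 17 without the ZT20 libraries, both chosen after seeing the data. Of the alternatives chosen before, the replicate block, partly confounded with time, gave 31 and VAT libraries fitted alone 42. Leaving out 1 library gave 54 to 1008. Of the genes named here by amplitude, Tef and Fkbp4 still passed with the slope.

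As groups in VAT, the scores of 4 lists followed the 24 h cycle by permutation. Glucocorticoid-responsive genes peaked at ZT12.3 with a score amplitude of 0.43 (adjusted permutation p = 0.00799), with 8 of 13 members called when adjusted over the list alone and 3 over all genes: Tsc22d3, the glucocorticoid-induced leucine zipper gene (0.84 ± 0.16, peak ZT12.3), Txnip (0.81 ± 0.17, ZT11.01) and Fkbp5 (0.81 ± 0.19, ZT14.44). The core clock score peaked at ZT10.9 (0.40, adjusted permutation p = 0.00799). Cold-inducible genes peaked at ZT7.1 (0.48, adjusted permutation p = 0.0418; 1 of 3 members, Rbm3, adjusted over the list alone and 0 over all genes by edgeR). Oxidative phosphorylation genes peaked at ZT20.5 (0.46, adjusted permutation p = 0.0418), with 15 of 23 members adjusted over the list alone and 5 over all genes, such as Cox7a2 (1.03 ± 0.21, ZT21.75), Ndufa9 (0.72 ± 0.16), Sdhb (0.55 ± 0.13) and Atp5o (0.61 ± 0.14). That last list had an adjusted permutation p of 0.126 with the length slope as a covariate and 0.38 without the ZT20 libraries. With detected genes as a covariate, cold-inducible (0.0733) and oxidative phosphorylation genes (0.0923) were both lost, so these 2 calls lay near the threshold. The other 13 lists were not called in VAT, with adjusted permutation p values from 0.0787 for activation and effector genes to 0.996 for lymphoid or resting Treg genes. Of these, sterol and fatty acid synthesis (amplitude 0.28, adjusted permutation p = 0.502) was called with the length slope as a covariate (0.69, peak ZT20.1, 0.0068) and with the length and GC slopes (0.72, 0.00875), where fatty acid oxidation was called too (0.0347).

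**Figure D2:**
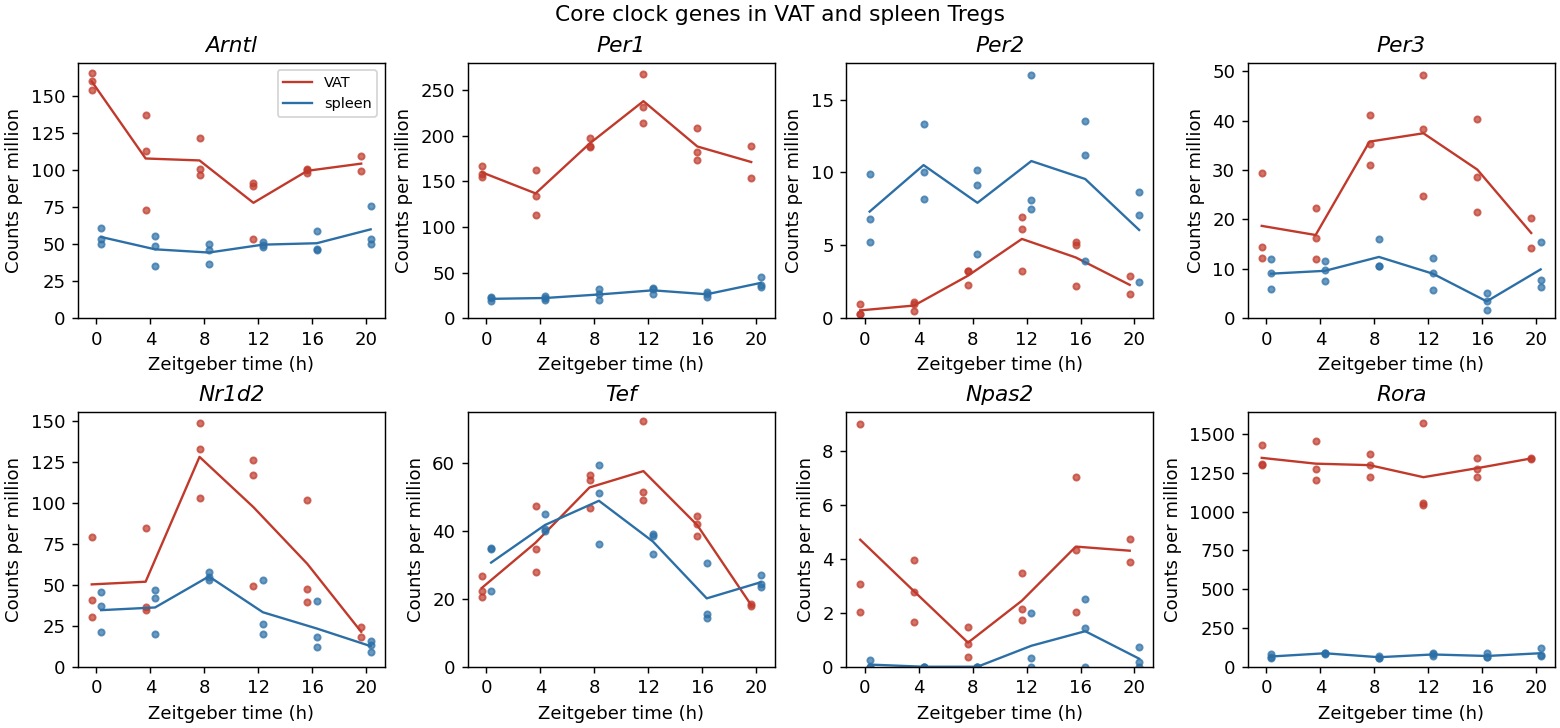
CPM of 8 core clock genes (y axes) against Zeitgeber time in hours (x axes) in VAT (red) and spleen (blue) Tregs, with 1 point per library and lines through the group means. Tef rose to 57.7 CPM at ZT12 in VAT and to 48.9 CPM at ZT8 in spleen, and Rora, with no rhythm called in either tissue, lay at 1300 CPM in VAT and 74.9 CPM in spleen.

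In spleen Tregs, Tsc22d3 (chromosome X, 140539528 to 140600659) had the clearest rhythm among the named genes, from 225 CPM at ZT0 to 683 CPM at ZT12, with an amplitude of 1.42 ± 0.16 and a peak at ZT12.64 (adjusted p = 2.61e-06, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The chaperone gene Hsp90ab1 peaked at ZT19.22 (1.00 ± 0.12, adjusted p = 2.37e-05) and Dusp1 (chromosome 17, 26505590 to 26562128) at ZT14.36 (1.23 ± 0.16, adjusted p = 7.88e-05), by the same edgeR test. Il7r, the receptor gene for a T cell survival cytokine, peaked at ZT13.77 (0.76 ± 0.13) and Junb at ZT15.78 (0.74 ± 0.12). Of the core clock, Tef (1.18 ± 0.20, peak ZT6.54) and Npas2 passed over all genes, the latter at a mean of only 0.411 CPM. Adjusted over the list alone 4 of 19 passed, with Nr1d2 (1.62 ± 0.43, ZT6.93) and Per1 (0.56 ± 0.17, ZT16.39). By edgeR over the list with the length slope, Nr1d2 fell to an amplitude of 0.75 (0.0336), Per1 was lost (0.302) and Dbp was gained (1.18, 0.0336). With the length and GC slopes Nr1d2 (0.119) and Per1 (0.124) were lost, and without the ZT20 libraries Nr1d2 was (0.309). Arntl had an amplitude of 0.39 ± 0.17 in spleen and did not pass, nor did the other 14 genes of the list. Its difference in rhythm between the tissues was not called either (adjusted p = 0.114 by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over the list alone), but was called in the same edgeR test with the length slope (0.0349) and with the length and GC slopes (0.0325), both chosen after seeing the data.

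Spleen Tregs had 316 rhythmic genes (2478 at an unadjusted p under 0.05) by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, with a median amplitude of 0.86. 49 genes were called in both tissues, where 5.9 would be shared by independent lists. That value does not allow for the length slope, which followed time in both tissues (R squared 0.37 in VAT and 0.45 in spleen). The excess is therefore not shown to be a shared rhythm of the cells. The largest amplitudes were those of the phosphatase gene Dusp2 (chromosome 2, 127336159 to 127338376; 3.63 ± 0.68, peak ZT7.96), Lamp1 (3.05 ± 0.60, ZT7.11), Mgat2 (2.59 ± 0.52, ZT7.37), Nsun2 (2.17 ± 0.40, ZT7.29), and Rac1 (2.14 ± 0.43, ZT7.29). They were followed by Zdhhc7 (1.90 ± 0.40, ZT7.44), Aggf1 (1.86 ± 0.41, ZT6.75), Ankle2 (1.82 ± 0.40, ZT7.12), Prkch (1.79 ± 0.37, ZT7.37), and Clptm1l (1.77 ± 0.35, ZT8.19). Further down were Slc30a9 (1.77 ± 0.40, ZT6.94), Kdm4b (1.74 ± 0.28, ZT7.23), Btaf1 (1.67 ± 0.31, ZT6.62) and Brap (1.65 ± 0.35, ZT7.12). All of these peaked between ZT6.62 and ZT8.19, and Dusp2 rose from 26.8 CPM at ZT0 to 340 CPM at ZT8. With the length slope in the model the count fell to 91, 75 of them among the 316, and Dusp2, Mgat2, Nsun2 and Kdm4b still passed.

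The scores of 7 lists followed the 24 h cycle in spleen by permutation. Sterol and fatty acid synthesis genes peaked at ZT6.2 with a score amplitude of 0.68 (adjusted permutation p = 0.00119). Of 22 members 7 were called when adjusted over the list alone and 3 over all genes, among them Cyp51 (1.16 ± 0.21, peak ZT5.52) and Sqle (1.16 ± 0.22, ZT6.93). With the length slope only Cyp51 and Sqle passed over the list (adjusted p = 0.0169 each by edgeR). No member then passed over all genes (Cyp51 0.0886, Sqle 0.111). Glucocorticoid-responsive genes peaked at ZT12.6 (0.53, adjusted permutation p = 0.00926; 8 of 13 adjusted over the list alone, 4 over all genes), with Pik3ip1 (0.63 ± 0.15) beside Tsc22d3, Dusp1 and Il7r. Cold-inducible genes peaked at ZT8.2 (0.57, adjusted permutation p = 0.0237; Rbm3 of 3 members both ways). Oxidative phosphorylation genes peaked at ZT17.7 (0.39, adjusted permutation p = 0.0186; 11 of 23 adjusted over the list alone, 2, Cox6a1 and Sdhb, over all genes). The Treg core (peak ZT18.7, adjusted permutation p = 0.0237; 4 of 12 adjusted over the list alone, 0 over all genes), lymphoid or resting Treg (ZT15.4, 0.0237; 0 of 14 both ways) and immediate early lists (ZT13.5, 0.044; 9 of 20 adjusted over the list alone, 1, Junb, over all genes) made up the rest. With the length slope as a covariate, the adjusted permutation p was 0.319 for oxidative phosphorylation, 0.345 for Treg core, 0.17 for lymphoid or resting Treg and 0.17 for immediate early genes, and with the length and GC slopes none of the 7 lists was called, the sterol list at 0.154. The other 10 lists were not called in spleen, with adjusted permutation p values from 0.0813 for activation and effector genes to 0.91 for lipid uptake and storage genes, and 0.0917 for the core clock and 0.0872 for heat shock genes. Without the ZT20 libraries heat shock genes were called (0.00521, score amplitude 1.07 against 0.59), and immediate early (0.0819), Treg core (0.238) and oxidative phosphorylation genes (0.0696) were lost. The call of immediate early genes was also lost with detected genes as a covariate (0.0593).

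The libraries themselves differed along 1 axis related to transcript length. The first principal component took 40.7% of the variance between VAT libraries and 36.4% between spleen libraries, and followed the length slope with Pearson's r of 0.996 and 0.988 and Spearman's rho of 0.975 and 0.942 (permutation p = 1e-05 for each of the 4, the smallest these permutations can give, and the same after adjustment over the 2 tissues). Without the 2 libraries farthest from the median slope, r was 0.992 and 0.978. Slope and component were computed from the same log2 CPM deviations. These correlations therefore do not show that length, rather than another trait of the genes such as GC content, sets the axis. The slope followed the 24 h cycle (R squared 0.37 in VAT, adjusted permutation p = 0.0394; 0.45 in spleen, 0.0262). The VAT libraries of ZT20 also had the highest shares of mitochondrial counts in VAT, 1.89% and 1.47% against 0.88% to 1.27% in the others, and the highest GC slopes, 1.074 and 1.005 against at most 0.571. In spleen the mitochondrial share was highest in ZT16 B (2.2%), ZT20 B (2.18%), ZT12 B (2.11%) and ZT20 C (2.1%). Rhythmic genes that peaked between ZT18 and ZT2 had a median transcript length of 1240 nt in VAT and 1472 nt in spleen, and those that peaked between ZT6 and ZT14 had 2904 and 2781 nt.

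**Figure D3:**
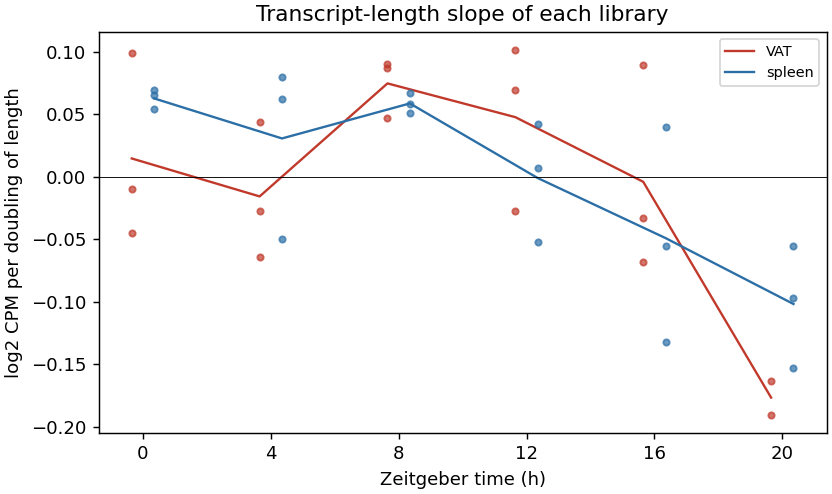
Transcript-length slope of each library, in log2 CPM per doubling of transcript length (y axis), against Zeitgeber time in hours (x axis) in VAT (red) and spleen (blue), with 1 point per library and lines through the group means. The VAT libraries of ZT20 lay at -0.19 to -0.16, below all other VAT libraries at -0.07 to 0.10.

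Whether the course over time differed between VAT and spleen was tested gene by gene and by list. Cyp51, an enzyme of cholesterol synthesis (chromosome 5, 4081145 to 4104746), was the 1 gene of 15910 called (1447 at an unadjusted p under 0.05): it peaked at ZT18.8 in VAT (0.69 ± 0.21) and at ZT5.52 in spleen (1.16 ± 0.21; adjusted p = 0.0321, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Next came Sqle, of the same pathway (chromosome 15, 59315077 to 59331192), with peaks at ZT20.52 and ZT6.93 and an adjusted p of 0.0621, Dusp1, Msmo1 and Junb (each 0.0679), Zw10 (0.0977), AA467197, Tef and Map2k5 (each 0.104) and Cd96 (0.118) by the edgeR test, none of them past the threshold. The sterol and fatty acid synthesis score differed in its course between the tissues by 0.96 (permutation p = 1e-04, adjusted p = 0.0017), in a test added after seeing the data, with 8 of 22 members called when adjusted over the list alone and 1 over all genes. The other 16 lists were not called, with adjusted permutation p values from 0.345 to 0.879. Of their members outside the core clock, 7 passed by edgeR over their own list: Dusp1, Junb, Atf3, Nr4a3, Tnf, Cd69 and Gbp2. Of the core clock 4 genes, Npas2, Per2, Per3 and Tef, differed in rhythm when adjusted over the list alone and 0 over all genes, where voom and DESeq2 over all genes called 2 and 22 genes of any kind. With the length slope 5 clock genes were called over the list, 3 of them among these 4: Per3 was lost (adjusted p = 0.0557 by edgeR) and Arntl and Cry1 (0.0282) were gained. With the length and GC slopes Per3 passed (0.04), as did Per1 (0.0325). With the replicate block Npas2 was lost (0.0897). The difference amplitude of Cyp51 was 1.82, and 1.67 to 1.86 in the alternatives that give one. Its edgeR adjusted p was 0.0597 with relative log expression factors, 0.0781 with library totals and 0.164 for any difference between the 6 times, and 1.83e-08 to 0.0368 in the other alternatives. Without 1 library the amplitude was 1.7 to 1.97, and the call ended for 12 of the 35 libraries (adjusted p up to 0.116).

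**Figure D4:**
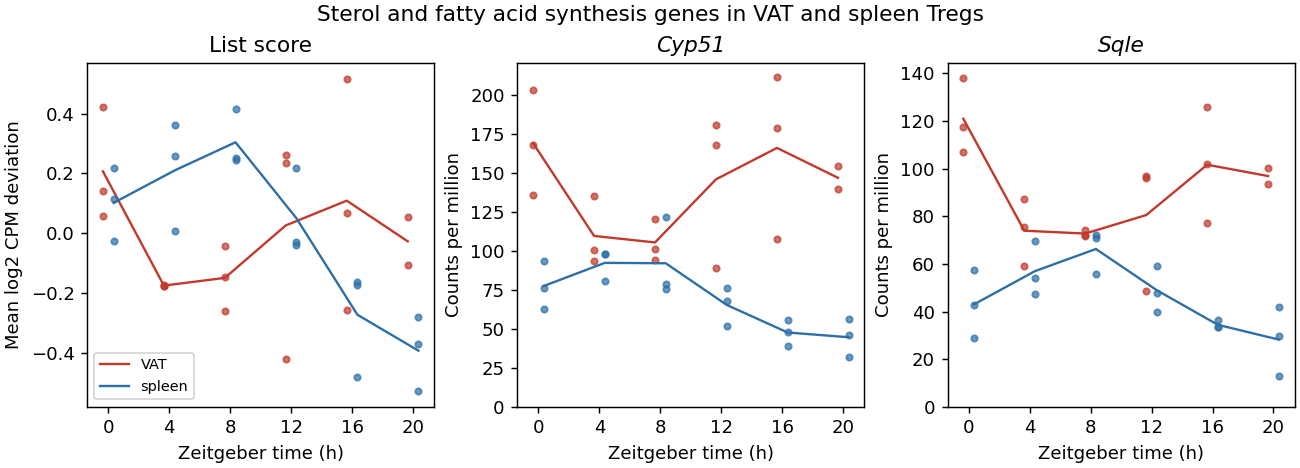
Score of the sterol and fatty acid synthesis list (mean log2 CPM deviation from each gene's mean in the tissue) and CPM of Cyp51 and Sqle (y axes) against Zeitgeber time in hours (x axes) in VAT (red) and spleen (blue), with 1 point per library and lines through the group means. In spleen Cyp51 was highest at ZT4 (92.4 CPM) and lowest at ZT20 (44.7 CPM), and in VAT it was lowest at ZT8 (106 CPM).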

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

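The tests of genes, of list scores over time within a tissue and the replicate block were chosen before their results were seen. The other tests below were chosen after the data were seen. Of these, the tests of a single library and of the ZT20 libraries for the sterol list were set before their own values were seen. They bear on a difference whose test was itself added after seeing the data. The criterion for handling before the sort was moreover rewritten after its values were known.

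Differences in rhythm between VAT and spleen, each by a test of the difference itself, brought 13 results here. The sterol and fatty acid synthesis score had an adjusted permutation p of 0.0017. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, Cyp51 had an adjusted p of 0.0321 over all genes. With edgeR p values adjusted over the core clock list alone, Npas2 had 0.00546, Per2 0.0047, Per3 0.0267 and Tef 0.00296. Over that list Per3 had 0.0557 with the length slope and Npas2 0.0897 with the replicate block, 0.152 with voom and 0.134 for any difference between the 6 times, and Arntl (0.0349) and Cry1 (0.0282) passed with the length slope. With the length and GC slopes Per3 had 0.04 and Per1 passed too (0.0325). Npas2 rested on a mean of 0.411 CPM in spleen and Per2 on 2.72 CPM in VAT. Leaving out 1 library ended the call of Per3 for 6 of 35 libraries, VAT ZT0 A and ZT4 B and spleen ZT0 B, ZT12 A, ZT16 B and ZT16 C (up to 0.0617).

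By the same edgeR test over their own lists, Dusp1 had 0.000294, Junb 0.000876, Atf3 0.00578, Nr4a3 0.00578, Tnf 0.00901, Cd69 0.0293 and Gbp2 0.0477, while the scores of these lists were not called. Dusp1, Junb and Tnf passed in each of the 12 alternatives that give this value and without each library. Atf3 was lost with voom (0.614), with the block (0.0618) and without spleen ZT12 A (0.422), and Nr4a3 with voom (0.114). Cd69 was lost in 6 of 12 alternatives (up to 0.17) and for 13 of 35 libraries, and Gbp2 in 5 (up to 0.104) and for 24.

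The first pattern is the number of rhythmic genes, 299 in VAT and 316 in spleen, beside a transcript-length trend between libraries that itself followed time. With the length slope in the model 21 of the VAT genes and 75 of the spleen genes stayed called, so the trend may account for many calls in both tissues. In 40 permutations of the times in which the slope followed time at least as strongly as in the real order (R squared from 0.37 in VAT and 0.45 in spleen), as many genes were called in 6 for VAT and in 2 for spleen. The medians were 59 and 3.5 genes, and the highest 1647 and 936. The trend without any other relation to time is therefore not excluded, although it mostly gave fewer genes, and the 2 in spleen (0.73 and 0.77) and 5 of the 6 in VAT (0.58 to 0.69) followed the slope more strongly than the real order, and the sixth in VAT at 0.39. The median amplitude of the called genes went from 0.74 (quartiles 0.61 to 0.99) to 0.47 (0.33 to 0.76) in VAT and from 0.86 (0.63 to 1.31) to 0.60 (0.40 to 1.13) in spleen, while the median SE of the amplitude went from 0.16 to 0.15 in VAT and from 0.18 to 0.16 in spleen. The amplitude fell in 271 of the 299 and 270 of the 316 genes, so calls mostly ended as amplitudes shrank, since the median error did not widen. The core clock calls in VAT argue against the trend as their whole cause: 6 of 7 stayed called when adjusted over the list alone. A daily change in the cells' RNA that favours short transcripts would also give this slope, was not tested, and stays open.

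The second pattern is the higher level of immediate early genes in VAT. Macrophages, neutrophils, stromal cells, adipocytes or B cells in the sort were judged by Lyz2, S100a8, Col1a1, Adipoq and Cd79a. These genes were chosen after the data were seen. The highest of them reached 0.0307% of the Fos level in VAT. Other members of the marker lists were far higher in VAT, where Fos averaged 6000 CPM. Mmp9 (450 against 10.1 CPM in spleen), Gsn (102 against 28.1 CPM) and Lrrn4 (91.8 against 3.67 CPM) were higher than in spleen. Ighm was lower than in spleen (159 against 1800 CPM). The reading therefore depends on the markers chosen, and such cells are not excluded. The mesothelial gene Msln was at 0.0604 CPM and Upk3b at 0.196 CPM in VAT. The lowest VAT library for Fos held 4560 CPM, above every spleen library, which handling of the tissue before the sort and the tissue itself would both give. These cannot be told apart, because the labels do not vary handling within a tissue, so a difference between Tregs living in VAT and spleen stays open and untested. The same limit holds for the other genes and lists compared between the tissues.

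The third pattern is the sterol and fatty acid synthesis list, whose score peaked at ZT6.2 in spleen and differed in its course from VAT by 0.96. The length trend as the whole cause is argued against by an adjusted permutation p of 0.00595 (size 0.70) with the slope removed, a single library by a highest permutation p of 4e-04, without VAT ZT0 A, VAT ZT0 B or spleen ZT20 A, and the ZT20 libraries by a permutation p of 3e-04 without them. In separate draws of permutations, adjusted over the 17 lists, the adjusted p was at most 0.0068 without 1 library and 0.0136 without ZT20. With the length and GC slopes removed the size fell to 0.58 and the adjusted permutation p was 0.0357, so part of the difference may come from these trends, and the spleen rhythm alone was then not called (0.154). The VAT score, not called at first (0.28, adjusted permutation p = 0.502), was called with the length slope (0.69, 0.0068) and with both slopes (0.72, 0.00875). A biological difference between the tissues was not tested in other ways and remains a hypothesis.

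Other splits of the samples tested whether chance can be excluded. For VAT against spleen, 1 of 40 splits of the tissue labels within each time, the real one, gave as many as 9896 genes, and the highest other gave 0 by edgeR. For rhythm in VAT 1 of 100 splits of the times, the real one, gave as many as 299 genes, with 25 the highest other, and in spleen 1 of 100 gave as many as 316, with 13 the highest other. Chance between libraries taken as independent is excluded at that level for these 3 counts, for rhythm over splits not chosen by the length slope. The labels do not say that libraries of a group came from separate animals. Chance differences between collections are therefore not excluded. For the difference in rhythm 34 of 100 splits gave 1 gene or more, with 7 the highest other, so chance is not excluded for the single call of Cyp51.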

How the results depend on the processing

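The tests with the transcript-length slope, the length and GC slopes, without the ZT20 libraries and with library totals were chosen after seeing the data, the other alternatives before. The tissue comparison gave 9142 to 11370 genes in the alternatives that kept the same filter and threshold. With library totals the share of called genes higher in VAT fell from 45.7% to 25.1%, and 8366 of the 9896 genes were shared. It gave 4295 genes at an average log2 CPM of at least 5 and 4740 with a 2-fold minimum, where fewer genes could pass by construction. With library totals 660 called genes turned direction, 15 of them list members. Of the genes named for the comparison between tissues, Rbm3 (-0.04) and Srsf5 (-0.19) did. The core clock count between tissues was 7 at an average log2 CPM of at least 5. The number of lists called between tissues stayed between 9 and 16. Heat shock, Treg core and glycolysis genes lost their call with library totals (camera adjusted p = 0.105, 0.0796 and 0.105) and, with sterol genes, at an average log2 CPM of at least 5 (0.608, 0.177, 0.0837 and 0.164 for sterol). Heat shock genes also lost it with the length and GC slopes (0.0533) and without ZT20 (0.078).

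The rhythm counts depended on the setting. In VAT and spleen they were 1572 and 1446 with no filter, 28 and 91 with the length slope, 23 and 37 with the length and GC slopes, 539 and 775 with voom, 675 and 854 with DESeq2, and 42 and 584 with each tissue fitted alone. In VAT they were also 501 at an average log2 CPM of at least 5, 128 with detected genes as a covariate, 17 without the ZT20 libraries, 196 with library totals and 813 for any difference between the 6 times. The difference in rhythm gave 1547 genes with no filter, 2 at an average log2 CPM of at least 5, 3 with the length slope, 2 with the length and GC slopes, 24 without the ZT20 libraries, 2 with voom and 22 with DESeq2. It gave 0 with relative log expression factors and 0 with library totals by edgeR. The core clock count in VAT was 4 at an average log2 CPM of at least 5 and 11 with voom. In spleen it was 9 with no filter, 2 with the length and GC slopes, 2 with voom, 7 for any difference between the 6 times and 2 with the tissue fitted alone. The lists called over time in VAT numbered 2 with detected genes as a covariate, and in spleen 3 with the length slope and 0 with the length and GC slopes. Oxidative phosphorylation in VAT lost its call with relative log expression factors (adjusted permutation p = 0.0598), library totals (0.096) and the length and GC slopes (0.119). Treg core in spleen lost its call with library totals (adjusted permutation p = 0.0616). The 1 list called for a difference in rhythm, sterol synthesis, stayed called in every setting run, with an adjusted permutation p of 0.00085 to 0.0357. Apart from the filters, and the length slope for rhythm in each tissue, under which amplitudes shrank, the cause was not tested. List tests were not run with voom, DESeq2, 5 degrees of freedom or the block, and list scores over time not with other filters.

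Among named genes and lists, the length slope ended 61 calls and gave 4, the length and GC slopes 72 and 5, leaving out ZT20 43 and 14, library totals 25 and 1, and DESeq2 2 and 43. Of the other alternatives chosen before, the replicate block ended 40 and gave 2, detected genes as a covariate 23 and 3. Each tissue fitted alone ended 22 and gave 7, and any difference between the 6 times 17 and 18. Relative log expression factors ended 9 and gave 5, no filter 4 and 78, and voom 3 and 25. With an average log2 CPM of at least 5 the numbers were 5 and 20. Leaving out single libraries ended 406 and gave 122, against 15045 that stayed on their side.

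Without 1 library the ranges were 9685 to 9864 genes between tissues, 54 to 1008 for rhythm in VAT, 98 to 569 in spleen and 0 to 11 for the difference. The core clock counts were 6 to 8 in VAT, 2 to 4 in spleen and 14 to 18 between tissues. The lists called were 13 to 13 between tissues, 2 to 4 in VAT, 3 to 9 in spleen and 1 to 1 for the difference. VAT rhythm gave 173 genes without ZT0 A, 1008 without ZT0 C, 196 without ZT4 C, 81, 151 and 186 without ZT8 B, C and D, 177 and 178 without ZT12 B and D, 549 without ZT16 B, and 54 and 79 without ZT20 A and C. Spleen rhythm gave 491 and 141 without ZT4 B and C, 158, 135 and 136 without ZT8 B, C and D, 569, 98 and 176 without ZT16 A, B and C, and 204 and 152 without ZT20 B and C. The spleen clock count was 2 without spleen ZT8 B, ZT20 A or ZT20 B. The difference gave 11 genes without VAT ZT0 C, ZT20 A or ZT20 C, 8 without spleen ZT12 A, 5 without VAT ZT0 A or spleen ZT16 A, 4 without spleen ZT20 B, and 3 without spleen ZT4 B. It gave 2 without VAT ZT4 B or spleen ZT0 C, ZT16 C or ZT20 A. It gave 0 by edgeR without VAT ZT4 C or D, ZT8 B, C or D, ZT16 A or B, or spleen ZT4 C or D, ZT8 B, ZT16 B or ZT20 C. The VAT lists numbered 2 without VAT ZT0 A, ZT4 C or D, ZT8 B, C or D, ZT12 A or B, or ZT16 A or C, and the spleen lists 3 without spleen ZT4 D.

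The values gave no sign that the replicate letters pair the libraries. Over 17 pairs of the same letter and time the correlation of deviations ran from -0.47 to 0.31 (median -0.02). Of these 2 were over 0.1, and 5 libraries correlated best with their own letter. Deviations within groups of 2 or 3 libraries also carry the length axis. They therefore cannot show that libraries of the same letter came from different animals. The block on letters gave 31 rhythmic genes in VAT and 222 in spleen, 9142 genes between tissues and 1 for the difference. For rhythm in a tissue it is partly confounded with time, so a lower count can come from the block itself. Depth limits the low genes: Npas2 in spleen averaged 0.411 CPM and Per2 in VAT 2.72 CPM, and amplitudes near 0.5 were mostly not detectable.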

Other observations

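The tests in this part all have the transcript-length slope in the model, an alternative chosen after seeing the data. The genes below other than Rbm3, Tsc22d3, Hsp90ab1, Cyp51 and Sqle were also named after their values were seen. With the slope, Rbm3, a cold-inducible RNA-binding protein gene, peaked at ZT8.2 in VAT (amplitude 0.79, adjusted p = 0.00266 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment) and at ZT7.5 in spleen (0.79, 0.000107). Tsc22d3 peaked at ZT11.9 in VAT (0.90) and ZT12.4 in spleen (1.40). The endoplasmic reticulum chaperone gene Hsp90b1 peaked at ZT21.4 in VAT (0.61) and ZT20 in spleen (0.64). Serinc3 peaked at ZT10.1 in VAT (0.73) and ZT12.4 in spleen (0.58).

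In spleen alone the slope left calls for Hsp90ab1 (0.97, peak ZT19.3), B2m (0.45, ZT18.5), Calr (0.55, ZT23), Pdia6 (0.62, ZT19.3) and Hspa5 (0.36, ZT21.3). In VAT alone it left calls for Ltb (0.62, ZT21.4), the T cell receptor kinase gene Lck (0.50, ZT20.1), Adgre5 (0.64, ZT11.9) and Rac2 (0.33, ZT18.6). A call in 1 tissue does not show a difference from the other. For the difference itself, Cyp51 (adjusted p = 0.000673) and Sqle (0.000856) were called by edgeR quasi-likelihood with the slope.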
